A study of Mus musculus with 10 samples.

How the data were processed

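Bulk RNA-seq libraries were made from 5 µg of total RNA with a TruSeq kit, per the labels, from PDAC cells collected by flow cytometry on surface PD-L1 after IFNγ stimulation. The submitters' processing notes name the genome build mm10 and CASAVA 1.7. The aligner, the counting tool, the annotation and the unit are not given in the sources used here. The authors deposited 1 table of normalized signal per gene with 10 library columns and 3 group means, and the means were not used. Whether the signal is TPM or FPKM is not stated and could not be decided from the values, so no count test was possible and depth per library is unknown. The library totals, 698396 to 715500, are set by that normalization and say nothing of depth.

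The deposited signal carries a pattern that no header or label explains. In 200 of 200 checked rows, all of low signal in every library, differences within groups among the 8 libraries other than untreated 3 and 4 followed a pattern. They were whole multiples, within 0.01, of 0.01 times 1 factor per gene (median 0.908, range 0.907 to 0.923). With all 10 libraries this held in 1 of 200. Rows of higher signal were not checked for this factor. The signal of 3390 of the 17808 rows above 0 in some library still had 2 decimals in all 10 libraries, 69 of them with a mean of at least 1. In the other rows with a mean of at least 1, the mean of untreated libraries 3 and 4 lay close to that of libraries 1 and 2. The median log2 difference was 0.0026, as values adjusted between 2 batches would give. Of the 69 rows, 13 were at 0 in untreated libraries 3 and 4 and above 0 in libraries 1 and 2. The spread within groups is therefore partly set by what produced this pattern, and tests against the untreated group are too liberal.

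Samples were grouped by their titles. The table held 25507 rows, of which 695 had no value and 24812 had values and were matched to mouse symbols. Rows sharing a symbol (52 symbols) were added up, a choice made after seeing the data. Genes with a mean signal of at least 1 over the 10 libraries were kept (11487). Values were transformed as log2(signal + 1), so that fold changes of low genes are understated, and no further scaling was applied. The design written before the data were examined named a count test if counts were found, and its branch for normalized values was used: limma (version 3.58.1, R 4.3.3) with an intensity trend and robust variances, 1 mean per group over all 10 libraries and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05.

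Gene lists (35, fixed before the data were examined) were tested with camera at a preset inter-gene correlation of 0.01, for lists with at least 3 tested members, and adjusted over 93 tests. The tests were repeated with an estimated correlation and with fry. Named genes followed a rule fixed in advance: 12 interferon and checkpoint genes always, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, up to 4 called members with the smallest adjusted p per list, and the 5 genes with the smallest p per class changed in both steps. Genes with only a predicted or clone name (Gm or Rik) and pseudogenes were left out, and 1 of the 12 genes is not reported here. Coordinates are from GENCODE for GRCm38, the assembly of mm10.

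The model was tested on simulated data with the residual spread of the real genes and 200 changed genes among 11487, without the alignment of the untreated libraries. In treated all against untreated all it recovered 66% of genes changed 1.25-fold, 90% at 1.5-fold and 100% at 2-fold, with 7 false calls. In PD-L1 high against treated all it recovered 58%, 88% and 100%, with 8 false calls. In PD-L1 high against untreated all it recovered 74%, 90% and 92%, with 5 false calls. When untreated libraries 3 and 4 were aligned to 1 and 2 in the simulation, false calls in the 3 comparisons rose to 82, 24 and 61, in the order above, and leaving these libraries out gave 5, 9 and 10. The factor found within groups was not simulated, so fits without these libraries may still be too liberal. Alternatives were other scalings, filters, pseudocounts, thresholds and sets of libraries, a block for replicate numbers and, chosen after seeing the data, fits without untreated libraries 3 and 4. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.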

Results

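RNA was sequenced from 10 libraries of mouse pancreatic ductal adenocarcinoma (PDAC) tumor cells, a cancer of the exocrine pancreas. Cells were stimulated with recombinant mouse interferon gamma (IFNγ) for 20 hours, per the labels, and collected by flow cytometry on surface PD-L1, the ligand of the T cell checkpoint receptor PD-1. The libraries fall into 3 groups: 4 without IFNγ over all PD-L1 levels (untreated all), 3 with IFNγ over all levels (treated all) and 3 with IFNγ and high PD-L1 (PD-L1 high). The comparisons address the response of unselected cells to IFNγ, and what set cells with high surface PD-L1 apart from cells of all levels. Treated all can itself hold cells with high PD-L1, and there is no group with low PD-L1, so this difference may be understated. The deposited values are a normalized signal per gene, whose unit is not given in the sources used here, so read depth is unknown. They summed to between 698396 and 715500 per library, and 11487 genes had a mean of at least 1 and were tested. Library profiles correlated at 0.987 to 0.992 within groups and at 0.941 to 0.987 between groups. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

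The 4 untreated libraries did not behave as 4 independent ones. The mean of untreated libraries 3 and 4 differed from that of libraries 1 and 2 by a median of 0.0026 on the log2 scale over the rows concerned, against 0.052 and 0.066 for the other pairings. In unchanged groups simulated with that alignment, 12% of genes had p under 0.05 in each comparison with the untreated group and 7.07% in PD-L1 high against treated all. The adjusted p-values below are therefore too small, and the total of changed genes in each comparison is followed by the total without these 2 libraries. The simulation left out the factor found within groups, so the totals without these libraries may also be too high.

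Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095, plus strand, GRCm38), had a signal of 2.58 ± 0.17 (SD, n = 4) in untreated all, 33.0 ± 0.71 (SD, n = 3) in treated all and 47.5 ± 1.2 (SD, n = 3) in PD-L1 high. The log2 fold change was 3.25 ± 0.05 (SE) with IFNγ (limma adjusted p = 3.5e-13). Cells were selected on the protein of this gene, so its difference of 0.51 ± 0.05 between PD-L1 high and treated all (adjusted p = 4.1e-05) checks the labels and is no finding. Pdcd1lg2, which encodes the other PD-1 ligand, stayed below the filter, at 0 in untreated all and PD-L1 high and at a mean of 0.027 in treated all.

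**Figure D1:**
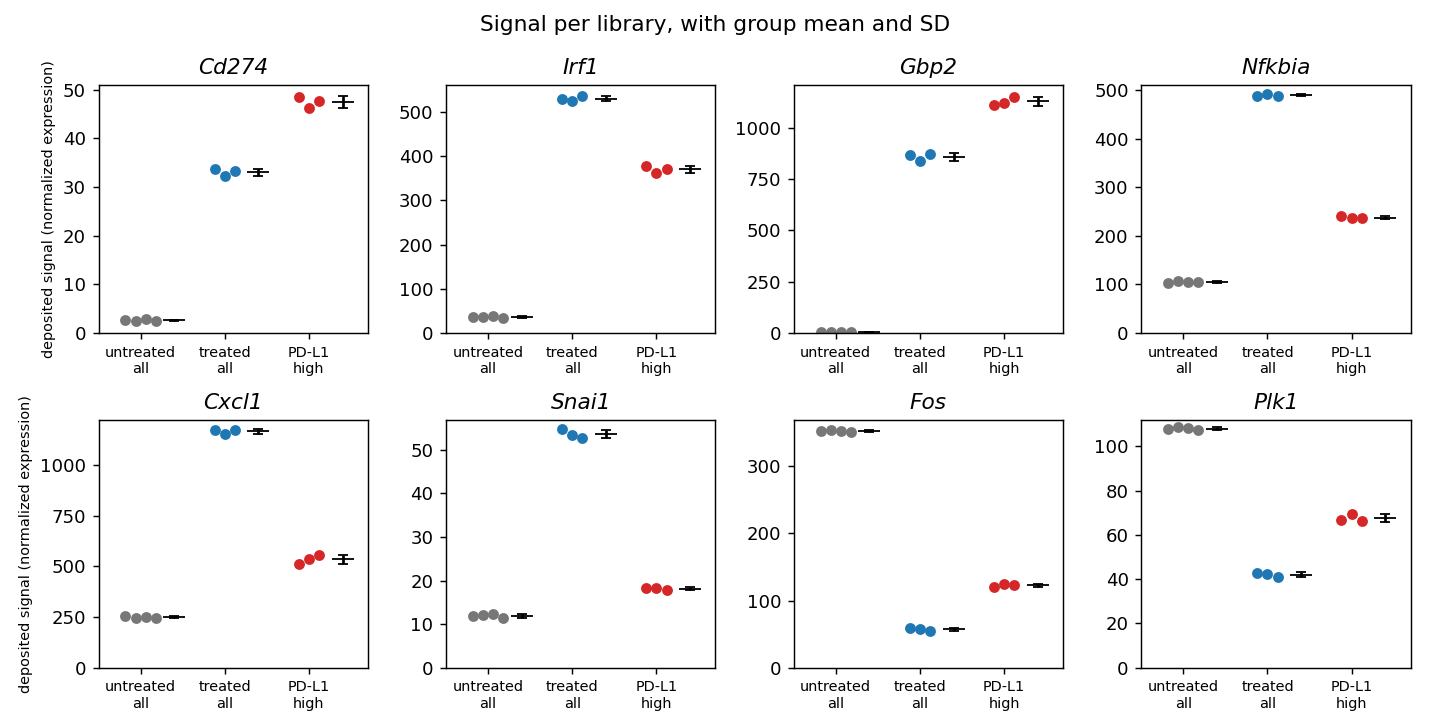
Deposited signal of 8 genes in each of the 10 libraries (points), with the mean and SD of each group beside them, on linear axes from 0. Cd274 and Gbp2 were higher in PD-L1 high than in treated all, while Irf1, Nfkbia, Cxcl1 and Snai1 were lower, and Fos and Plk1 in PD-L1 high lay between treated all and untreated all.

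With IFNγ, unselected cells turned on interferon target genes by large factors. The guanylate-binding proteins and immunity-related GTPases, which attack the vacuoles of intracellular pathogens, went from low values to some of the largest rises measured. Gbp3 went from 0.799 ± 0.19 to 376 ± 3.6, Gbp2 from 4.75 ± 0.52 to 857 ± 19 and Igtp from 3.8 ± 0.14 to 605 ± 0.46 (mean ± SD). Of the interferon-inducible GTPases, 21 of 23 measured members rose, 1 fell and 1 did not pass the test, with a median log2 fold change of 5.47 (camera adjusted p = 3.5e-23, but adjusted p = 0.0081 with an estimated correlation). The member that fell is a gene with only a RIKEN clone name, a kind left unnamed by rule. Gbp2b, Gbp4, Tgtp1 and Tgtp2 were also among the 10 largest rises, with log2 fold changes of 7.73, 7.31, 7.71 and 6.79; near-identical copies make the split between Tgtp1 and Tgtp2 uncertain. Zbp1, a sensor of Z-form nucleic acids, completed the 10 with Psmb8 and Psmb9, at a log2 fold change of 6.26.

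Genes of the IFNγ pathway itself rose as a group: 17 of 18 measured members rose, 0 fell and 1 did not pass the test (camera adjusted p = 2.7e-15). Irf1, a transcription factor of the interferon response, rose from 36.3 ± 2.2 to 530.1 ± 5.4. Batf2 was listed at 0 in the 4 untreated libraries and reached 36.6 ± 2.8 in treated all. Nlrc5, the activator of MHC class I genes, rose by a log2 fold change of 4.97 ± 0.06. Of the receptor genes, Ifngr1 changed by 0.13 and Ifngr2 by 0.60. The feedback inhibitor Socs1 rose from 1.68 ± 0.25 to 6.1 ± 0.54, and of the JAK-STAT feedback list 8 of 12 measured members rose, 0 fell and 4 did not pass the test (camera adjusted p = 1.2e-04). Of the antiviral interferon-stimulated genes 32 of 33 measured members rose, 0 fell and 1 did not pass the test (camera adjusted p = 3.2e-25), among them Bst2, a tether of budding virions, at 3.75 and Oasl2 at 4.09.

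Antigen presentation genes rose together. For MHC class I, 20 of 21 measured members rose, 0 fell and 1 did not pass the test, with a median of 2.98 (camera adjusted p = 3.2e-22). B2m, the light chain of class I molecules, went from 286 ± 1.8 to 3420 ± 37. The immunoproteasome subunits Psmb8 and Psmb9 rose by 6.58 and 6.54 on the log2 scale, and the heavy chain gene H2-D1, which shares sequence with other class I genes, by 3.94. For MHC class II, 7 of 9 measured members rose, 2 fell and 0 did not pass the test (camera adjusted p = 6.4e-06). Cd74, the invariant chain, went from 0.328 ± 0.034 to 43.9 ± 1.4, and Ciita, the class II transactivator, reached 4.91 ± 0.3 from 0.00557 ± 0.011. The 2 that fell, named after their values were seen, were the lysosomal enzyme genes Ifi30 and Ctsl, at −0.16 and −0.11. Both calls were lost with median-ratio and upper-quartile scaling, and that of Ctsl also without any 1 of 7 libraries.

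Secreted and immunoregulatory genes rose as well. Of the chemokines and cytokines 17 of 22 measured members rose, 3 fell and 2 did not pass the test (camera adjusted p = 7.9e-10). The T cell attractants Cxcl10 and Cxcl9 reached 99.96 ± 1.4 and 2.91 ± 0.54, from 1.87 ± 0.25 and 0.0225 ± 0.033. The neutrophil attractants Cxcl1 and Cxcl2 rose by 2.22 and 3.01 on the log2 scale. The 3 that fell, named after their values were seen, were Il33, Tgfb1 and Tgfb2, at −1.06, −0.18 and −0.38, with the call of Tgfb1 lost with median-ratio scaling. Of the checkpoint and immunosuppressive genes 11 of 17 measured members rose, 1 fell and 5 did not pass the test (camera adjusted p = 7.9e-06), with Ido1, which degrades tryptophan, going from 0.0461 ± 0.039 to 16.9 ± 0.81 and Fgl1, the member that fell, at −0.46 (named after its value was seen). Of the cell death genes 20 of 28 measured members rose, 4 fell and 4 did not pass the test (camera adjusted p = 4.7e-09), including Mlkl, the effector of necroptosis, at 1.60. Of the NF-kB targets 19 of 19 rose (camera adjusted p = 2.4e-14), with the inhibitors Nfkbia at 2.21 and Tnfaip3 at 2.45. Adjusted over the list alone, the counts of these and the interferon and MHC lists were the same except for chemokines and cytokines, with 18 risen, and cell death genes, with 21 risen.

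Of the unfolded protein and integrated stress response 15 of 18 measured members rose, 1 fell and 2 did not pass the test, with a median of 0.42 and with Ddit3, a stress-induced transcription factor, at 1.86 (camera adjusted p = 6.6e-09). Ferroptosis and redox genes had 12 of 17 members risen and 1 fallen, cholesterol and fatty acid synthesis 13 of 20 and 2, and glycolysis 12 of 20 and 5 (camera adjusted p = 2.0e-05, 7.0e-05 and 0.0074). Adjusted over the list alone, these counts and those of the next 2 lists did not differ. Hypoxia genes (8 of 17 risen, 3 fallen) and amino acid and kynurenine genes (8 of 12 risen, 4 fallen) were called with camera, but adjusted p = 0.21 and 0.061 with an estimated correlation.

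Cell cycle genes were the main list on the falling side: 7 of 36 measured members rose, 23 fell and 6 did not pass the test (camera adjusted p = 1.2e-05, but adjusted p = 0.058 with an estimated correlation). Adjusted over the list alone, 24 fell, while the counts of the following lists were unaffected. The mitotic kinase Plk1 fell from 108 ± 0.56 to 42.1 ± 0.97, and the log2 fold changes of the proliferation marker Mki67 and of Ube2c, a ubiquitin-conjugating enzyme of mitosis, were −1.73 and −1.13. Of the RAS-MAPK and YAP output genes 3 of 18 measured members rose, 14 fell and 1 did not pass the test (camera adjusted p = 0.014, but adjusted p = 0.17 with an estimated correlation). Only 18 of the 20 listed symbols were found. The list holds Cyr61, an older symbol of Ccn1, which was measured and fell (below) but is not in these counts. Among the largest falls were U90926, from 231 ± 3.0 to 3.6 ± 0.81, and the immediate early genes Fos, Egr1 and Dusp1, at −2.60, −2.10 and −2.04. The immediate early and heat shock list as a whole had 9 members risen and 13 fallen of 24 (camera adjusted p = 0.46). The remaining large falls were in Pagr1a, Ccdc191, Exosc6, Spink4, Kifc5b and the histone gene H2ac18, with a wide spread in untreated Ccdc191 (21.8 ± 12); the call of H2ac18 was lost without untreated libraries 3 and 4.

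Known regulators of PD-L1 went both ways: 6 of 23 measured members rose, 12 fell and 5 did not pass the test (camera adjusted p = 0.44), with Myc at −0.46 and the glycosyltransferase B4galt1 at 0.41. Mesenchymal genes had 4 risen and 13 fallen members of 21 (camera adjusted p = 0.12), with Fn1, which encodes fibronectin, at −0.95.

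In all, 7106 of 11487 genes changed in treated all against untreated all (limma, Benjamini-Hochberg adjusted p under 0.05), 2648 higher and 4458 lower, of which 323 and 165 changed by at least 2-fold. Without untreated libraries 3 and 4, 5465 genes were called. Median-ratio scaling turned the split to 3538 higher and 3469 lower, and upper-quartile scaling to 3114 and 3865, so the size of the excess of lower genes depends on the scaling.

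**Figure D2:**
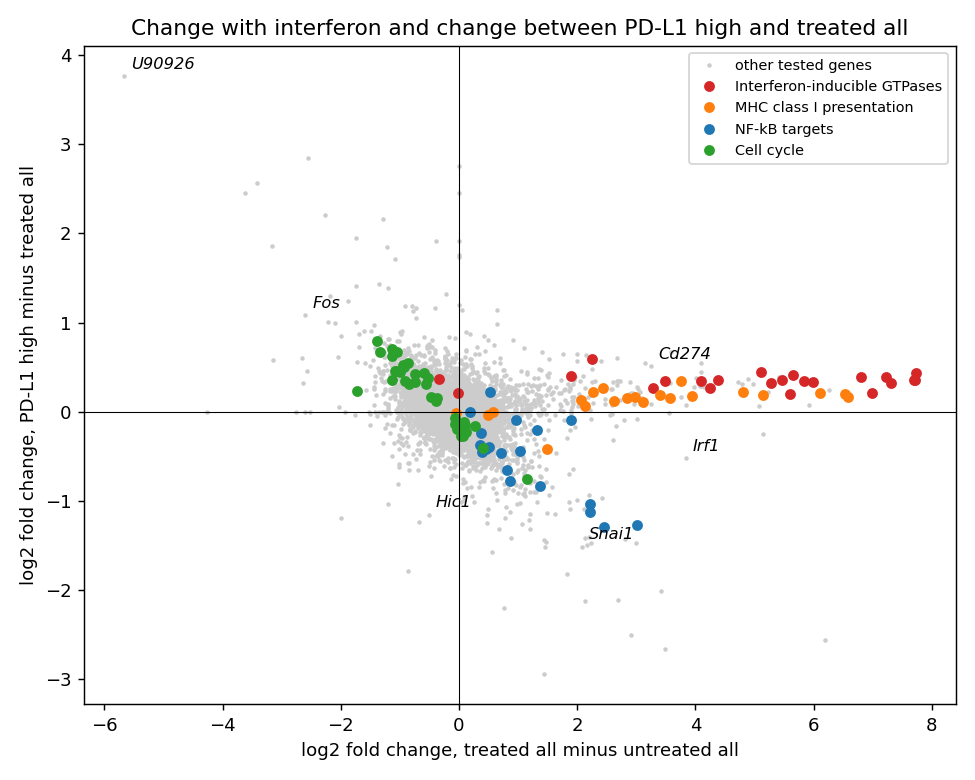
Log2 fold change of each tested gene with IFNγ (x axis, treated all minus untreated all) and between PD-L1 high and treated all (y axis). The interferon-inducible GTPases and MHC class I genes lie mostly at the upper right, NF-kB targets at the lower right and many cell cycle genes at the upper left.

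Compared with treated all, PD-L1 high cells had more of most interferon-induced GTPase and of many antiviral and MHC class I transcripts and less of NF-kB target, chemokine and stress transcripts, with differences below 2-fold for most genes. Of the GTPases 19 of 23 measured members rose, 0 fell and 4 did not pass the test, with a median of 0.35 (camera adjusted p = 6.6e-12). With the estimated correlation of this list, 0.20 against the preset 0.01, the camera adjusted p was only 0.037. Gbp2 was at 1127 ± 21 against 857 ± 19 and Irgm1 at 474 ± 0.14 against 372 ± 3.6. Of the antiviral genes 15 of 33 measured members rose, 0 fell and 18 did not pass the test (camera adjusted p = 3.4e-06), with Ifit3 at 0.67 and Oasl2 at 0.45. Of the MHC class I genes 11 of 21 measured members rose, 0 fell and 10 did not pass the test (camera adjusted p = 6.4e-06), with B2m at 0.15 and the nonclassical heavy chain H2-T23 at 0.34. Adjusted over the list alone, 21, 17 and 13 members of these lists rose, and 1 antiviral gene fell.

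The IFNγ pathway did not pass camera as a list: 4 of 18 measured members rose, 2 fell and 12 did not pass the test (camera adjusted p = 0.12). With fry, which does not compare a list with other genes, the adjusted p was 0.0087. It also passed camera when a replicate block was added (camera adjusted p = 0.033). Irf1 was lower in PD-L1 high, at 370.2 ± 8.3 against 530.1 ± 5.4 (adjusted p = 9.6e-06). Socs1 was higher, at a log2 fold change of 0.67, and Socs3 lower, at −0.64. Of 9 measured MHC class II genes, 1 rose, Ctsl at 0.17, with its call lost without treated all library 3, PD-L1 high library 2 or 3 or untreated libraries 3 and 4 together. Cd74 and Ciita differed by 0.06 and −0.03, with adjusted p of 0.36 and 0.82. Ifngr1 differed by 0.03 (adjusted p = 0.33), and Ifngr2 was lower, at −0.25, a call lost without library 1 of either group. Of the checkpoint and immunosuppressive genes 6 of 17 measured members rose, 5 fell and 6 did not pass the test (camera adjusted p = 0.3), or 7 risen adjusted over the list alone. Ido1 was higher, at 25.1 ± 1.4 against 16.9 ± 0.81, and so was Nos2, which makes nitric oxide, at 0.60, while Ptgs2, which makes prostaglandins, and Pvr were lower, at −0.59 and −0.31. Cxcl9 differed by 0.39 and Cxcl10 by −0.25; the call of Cxcl9 was lost without treated all library 2 or PD-L1 high library 2 or 3, and that of Cxcl10 without library 1 or 3 of either group.

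NF-kB targets were lower in PD-L1 high: 15 of 19 fell, 4 did not pass the test and the median was −0.45 (camera adjusted p = 2.2e-13). Nfkbia was at 238 ± 2.4 against 489.8 ± 1.7 and Tnfaip3 at 40.0 ± 0.3 against 99.7 ± 2.9. Of the chemokines and cytokines 3 of 22 measured members rose, 13 fell and 6 did not pass the test (camera adjusted p = 5.4e-04), with Cxcl1 at −1.12, Cxcl2 at −1.27 and the cytokine Lif at −0.93. The other members that rose beside Cxcl9, named after their values were seen, were Ccl5 and Il18bp, at 0.65 and 0.18, with the call of Il18bp lost without any 1 of 5 libraries. Adjusted over the list alone, 4 chemokines and cytokines rose, and the NF-kB and IFNγ pathway counts were the same. The 10 largest falls also held Snai1, a transcription factor of epithelial-mesenchymal transition, from 53.6 ± 1.0 in treated all to 18.1 ± 0.31 (of 21 mesenchymal genes 8 rose and 5 fell, camera adjusted p = 0.19, or 9 risen adjusted over the list alone), and the stress-responsive genes Klf10, Gadd45b, Ddit4 and Tsc22d3, at −1.47, −1.43, −1.42 and −1.32. Ramp3, the histone gene H3c10 and the small nucleolar RNA Snord22 completed them; small RNAs are poorly captured by this kind of library, and the call of Snord22 was lost without any 1 of 8 libraries.

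Unfolded protein and integrated stress response genes (12 of 18 fell), ferroptosis and redox genes (10 of 17), cholesterol and fatty acid synthesis (9 of 20) and Myc targets and ribosome biogenesis (13 of 20) were lower in PD-L1 high, with no called member higher. Their camera adjusted p-values were 1.3e-06, 1.1e-04, 4.3e-05 and 2.3e-05. Adjusted over the list alone, 14, 11, 10 and 14 members fell, and 1 member each of the ferroptosis and Myc lists rose. Examples were Ddit3 at −1.02, the ferritin chain Ftl1 at −0.20, Insig1, a brake on sterol synthesis, at −0.64 and the nucleolar protein gene Nolc1 at −0.31. Classical pancreatic cancer genes had 7 of 12 fallen and 3 risen, with the duct transcription factor Sox9 at −1.19 (camera adjusted p = 0.0098, but adjusted p = 0.17 with an estimated correlation), or 4 risen adjusted over the list alone. Of 23 known regulators of PD-L1, 3 rose and 5 fell (camera adjusted p = 0.96), or 4 and 6 adjusted over the list alone, with the hypoxia factor Hif1a at −0.31 and Hip1r, which routes PD-L1 to lysosomes, at 0.24.

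Cell cycle genes were more often higher than lower in PD-L1 high against treated all. Of 36 measured members 23 rose, 10 fell and 3 did not pass the test (camera adjusted p = 3.4e-06, but adjusted p = 0.048 with an estimated correlation). Adjusted over the list alone, 12 fell. The list covers S phase and mitosis, and the examples that follow are mitosis genes. Plk1 was at 67.4 ± 1.8 against 42.1 ± 0.97, and Aurka and Ccnb1, a mitotic kinase and a mitotic cyclin, were at 0.71 and 0.67. U90926 and Fos, which fell with IFNγ, were higher in PD-L1 high by 3.77 and 1.09 on the log2 scale, and Egr1 was at 88.8 ± 2.2 against 44.0 ± 2.3. The immediate early and heat shock list as a whole had 5 members risen and 11 fallen of 24 (camera adjusted p = 0.14), or 6 and 12 adjusted over the list alone. Vmn1r4, Tcerg1l, Kifc5b, Ccnf, Lims2, Saa3 and Clec2d were the other large rises. Of these, Clec2d went from 19.3 ± 2.0 to 39.2 ± 2.3, and Vmn1r4 reached only 3.57 ± 2.8 and lost its call without library 1 or 3 of either group.

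The number of genes changed in PD-L1 high against treated all was 2943 of 11487, 1320 higher and 1623 lower, with 12 and 28 at 2-fold or more. Median-ratio scaling turned the split to 1597 higher and 1372 lower, and upper-quartile scaling to 1580 and 1368. Without untreated libraries 3 and 4, which enter only through the shared estimate of the spread, 1892 genes were called. In 6 of 19 symbols with a pair of rows the PD-L1 high values were closer to treated all when the rows were swapped, so whether the values of both groups were made in the same way is not settled. With an estimated correlation, 10 of the 11 lists called with camera in this comparison and 14 of the 18 called in treated all against untreated all held, the exceptions being those given above with that p.

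**Figure D3:**
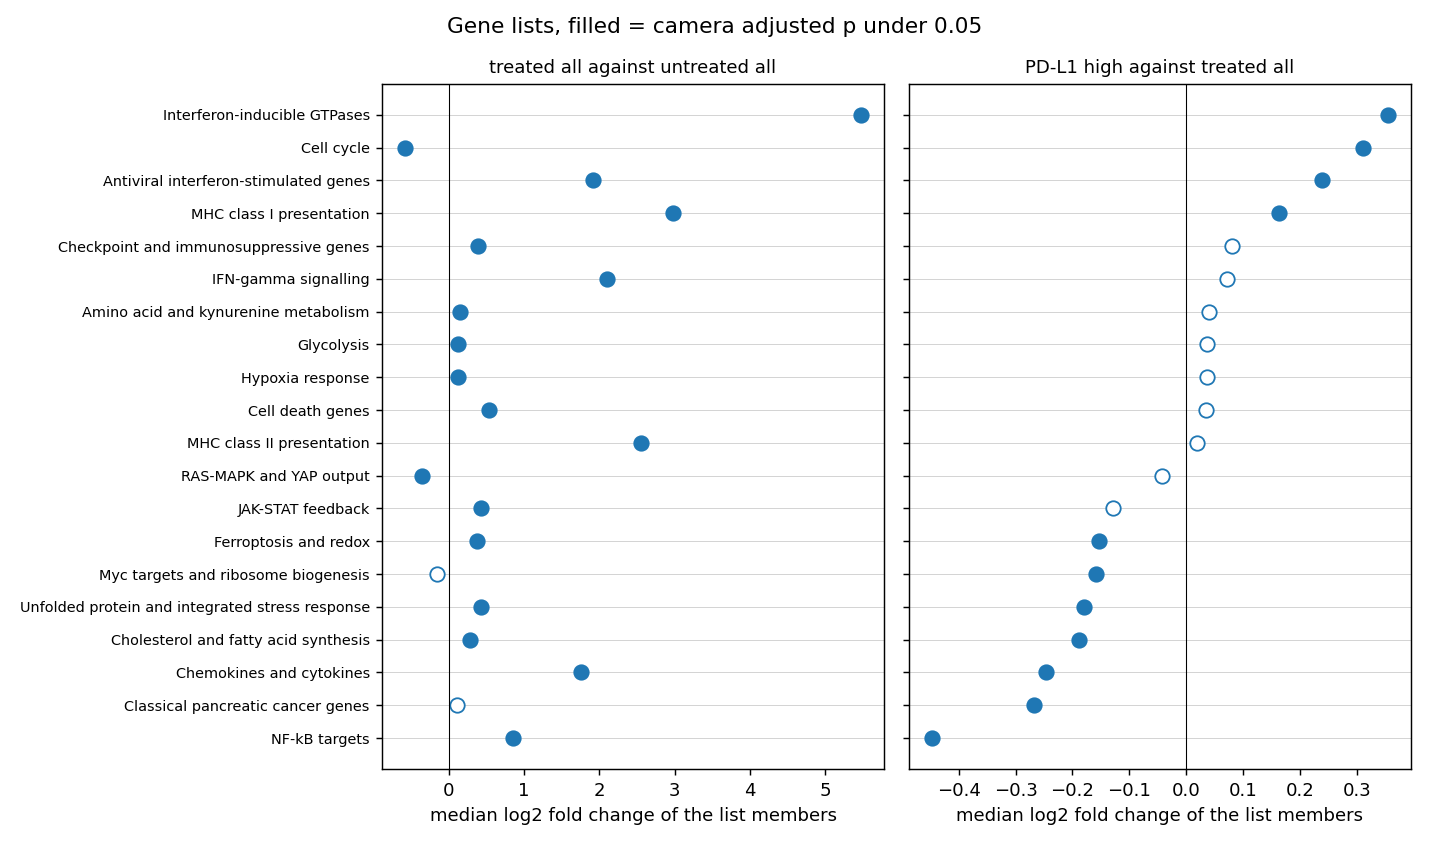
Median log2 fold change of the members of 20 gene lists in treated all against untreated all (left) and PD-L1 high against treated all (right), on separate linear axes. Filled points passed the camera test. The NF-kB targets were at 0.86 and −0.45 and the interferon-inducible GTPases at 5.47 and 0.35.

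In PD-L1 high against untreated all the interferon lists rose and the cell cycle list fell. Of the GTPases 22 of 23 rose, with a median of 5.80 (camera adjusted p = 1.2e-29, but adjusted p = 0.0058 with an estimated correlation). MHC class I genes had 19 of 21 members risen, or 20 adjusted over the list alone (camera adjusted p = 5.0e-26). The 10 largest rises were the same as in treated all, led by Gbp2b at 8.17 and Gbp3 at 8.07. NF-kB targets remained above the untreated level, with 15 of 19 risen and a median of 0.53 (camera adjusted p = 6.3e-09). Cell cycle genes were lower, with 30 of 36 fallen (camera adjusted p = 2.3e-07), and so were Myc targets and ribosome biogenesis genes, with 19 of 20 fallen (camera adjusted p = 3.0e-05); counts for the GTPases, cell cycle and Myc lists were the same adjusted over the list alone, and NF-kB targets then had 1 fallen member. U90926 was at 61.6 ± 9.9 against 231 ± 3.0, and Clca3b at 11.9 ± 0.45 against 49.8 ± 1.1. Cfd, Spink4, H3c10, H4c8 and Prr14l were among the 10 largest falls, with H2ac18, Pagr1a and Ccdc191; without untreated libraries 3 and 4 the calls of Cfd and H2ac18 were lost. The call of H2ac18 was also lost without any 1 of the 4 untreated libraries, treated all library 2 or PD-L1 high library 1 or 3.

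In total 6900 genes changed in PD-L1 high against untreated all, 2189 higher and 4711 lower, with 301 and 92 at 2-fold or more. Without untreated libraries 3 and 4, 5060 were called. Median-ratio scaling gave 3216 higher and 3154 lower, and upper-quartile scaling 2836 and 3633.

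Genes that changed in both steps mostly moved back. Of the 2648 genes that rose with IFNγ, 862 were lower in PD-L1 high than in treated all and 269 higher, where independent lists would share 374 and 304. Of the 4458 that fell, 848 were higher and 264 lower, against 512 and 630. Without untreated libraries 3 and 4 these 4 counts were 552, 176, 545 and 89, and median-ratio scaling gave 124 in place of 264. Nfkbia, Gdf15, Klf10, Cxcl1 and Snai1 rose and were then lower by the smallest p, and Slfn2, Plac8, Ly6a, Irgm1 and Tubb3 rose in both steps. Ccn1, Fos, Kpna2, Egr1 and Tuba1c fell and were then higher, and Plpp3, Sik1, Trib1, Hic1 and Btg2 fell in both, Hic1 from 8.92 ± 0.14 to 5.96 ± 0.11 to 2.13 ± 0.13. The treated libraries enter both steps with opposite sign, which alone pulls the steps apart: the correlation of the fold changes across genes was −0.27, against a mean of −0.54 in 100 simulations of unchanged groups, while the covariance was −0.040 against −0.012, a difference of −0.029. The simulated groups shared at most a mean of 0.010 calls per class, but unchanged groups give almost no calls. That count cannot show how much of the overlap comes from the shared libraries. The steps were not fitted with separate treated all libraries for each, so part of the excess may come from sharing them.

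The position of each library on the response was its mean log2 signal over the genes that rose with IFNγ, chosen with the treated all libraries. For a library of untreated all or treated all, the genes were chosen again without it. Treated all libraries 1, 2 and 3 were thus scored over 2399, 2568 and 2457 genes, and PD-L1 high over 2648. The position was 4.44 ± 0.013 in untreated all, 5.03 ± 0.061 in treated all and 4.91 ± 0.0024 in PD-L1 high (SD). PD-L1 high lay 0.12 below treated all on this score. Because the gene sets differ, neither this difference nor the wider spread of treated all can be read as a result. Over the fixed interferon lists, with the same genes for every library, PD-L1 high lay 0.19 above treated all (6.98 ± 0.0031 against 6.79 ± 0.034). Both differences had an exact permutation p of 0.10 (two-sided), the smallest that 3 against 3 libraries allow. For the first score this p is no test, since its gene sets differ between the groups.

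Few markers of other cell types were measurable. Of the listed markers 3 myeloid, 1 lymphocyte, 4 fibroblast or stellate, 1 endothelial, 3 acinar or endocrine and 0 erythroid genes passed the filter, and none of the tested lists passed camera in any comparison. With fry, the myeloid list passed in both comparisons with the untreated group (adjusted p = 3.7e-06 and 7.6e-07), the fibroblast and stellate list in PD-L1 high against treated all (adjusted p = 0.034) and the acinar and endocrine list in PD-L1 high against untreated all (adjusted p = 0.0043). Hbb-bs, a globin gene below the filter, was at 1.18 ± 0.18, 0.0958 ± 0.089 and 0.269 ± 0.27 in untreated all, treated all and PD-L1 high. Cd14, a myeloid marker that tumor cells can also express, was at 62.4 ± 1.1, 83.8 ± 0.97 and 93.6 ± 0.8 in untreated all, treated all and PD-L1 high. Amy2a5, an acinar amylase gene, was at 3.1 ± 1.1, 6.65 ± 2.1 and 12.2 ± 2.0, and its call in PD-L1 high against treated all was lost without any 1 of 6 libraries. No mitochondrial transcript was among the rows.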

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

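The tests of explanations and the splits of the libraries in this part were chosen after the results were seen.

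Dixon's test for an outlying library was run on the 4 untreated libraries for the genes named here. It singled out Ciita in library 3 (0.0223 against 0 in the others, ratio of gap to range 1), Exosc6 in library 2 (9.09 against 1.89 to 3.1, ratio of gap to range 0.832), Igtp in library 3 (4.001 against 3.72 to 3.74, ratio of gap to range 0.935), Psmb8 in library 2 (5.57 against 5.95 to 5.98, ratio of gap to range 0.928) and Tuba1c in library 3 (382 against 385 in the others, ratio of gap to range 0.937). These are 5 of 107 named genes, where 0.357% of all 11487 tested genes passed the critical value and chance flags about 5% of independent groups. Where libraries 3 and 4 have the same mean as 1 and 2, the ratio cannot reach the critical value. The low share over all genes therefore follows from the alignment, and a flagged gene is one whose means were not so matched.

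Genes that rose with IFNγ were more often lower than higher in PD-L1 high than in treated all. Chance values of the shared treated all libraries would give a covariance of the 2 steps between −0.017 and −0.0066 in 100 simulations, and −0.040 was observed, which argues against them as the whole cause. A trend with GC content or transcript length (known for 98.8% of genes) explained 0.808% of the variance of this step across genes, so its removal moved few values, and 66.0% of the risen genes lay lower after it, against 66.8% before, which argues against such a trend as the whole cause. Handling of the treated all libraries cannot be told apart from the groups: the immediate early and heat shock list had a median of −0.15 with members on both sides, and no source used here records handling. The selection on PD-L1, which the design names, stays open as an untested biological explanation.

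The interferon-inducible GTPases were higher in PD-L1 high than in treated all. Cells without a response in treated all would lower every strongly raised gene by 1 common factor, and 8 of 42 genes raised at least 16-fold (19.0%) differed from their median step of 0.32. Without single libraries 1 to 5 genes did (1 without treated all library 2, 2 without PD-L1 high library 1 or 3), and 2 without untreated libraries 3 and 4, so this explanation stays open. Reads shared between near-identical copies would leave the sum of the list unchanged, but the summed signal was higher by 0.34 ± 0.015 (SE) on the log2 scale. This argues against a shift of reads within the list as the whole cause. With 19 of 23 members higher and 0 lower the sum was bound to be higher, so it is no separate support. Other technical explanations were not tested, and a stronger response of the selected cells remains a hypothesis.

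The calls against the untreated group might rest on the alignment of untreated libraries 3 and 4 to 1 and 2. Without these libraries 5463 of the 7106 calls in treated all against untreated all (76.9%) were made again in the same direction. The direction was nearly fixed, since aligned means leave the fold changes much the same. That the calls passed again argues against the alignment of these 2 libraries as the whole cause, but the factor within groups remains in the others. How many of the other calls are due to the alignment stays open. In treated all against untreated all 1 of 35 splits of the 7 libraries, the real one, gave as many as 7106 genes, and the highest other gave 2. In PD-L1 high against untreated all it was 1 of 35, with 6900 and 2. Both shares are under 0.05, but they count only as far as the libraries are separate samples. The alignment leaves that open for the untreated group, and the labels name no separate cultures in any group, so chance is not excluded. For PD-L1 high against treated all the 10 splits are too few for a share under 0.05; the real split gave 2943 genes and the highest other 2.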

How the results depend on the processing

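The alternatives without untreated libraries 3 and 4, the batch term, the separate treatment of shared symbols and median-ratio scaling of lists and overlaps were chosen after seeing the data. Leaving out each library in turn gave 6509 to 7139 genes in treated all against untreated all, 2414 to 2896 in PD-L1 high against treated all and 6187 to 6990 in PD-L1 high against untreated all, so no single library moved a count by over 1.5 times; Cd274 ranged from 3.22 to 3.28, 0.49 to 0.53 and 3.74 to 3.79 on the log2 scale. With pseudocounts of 0.1 and 5 it was 3.63 and 2.33, 0.52 and 0.47, and 4.15 and 2.79. In PD-L1 high against treated all the count fell to 1892 without untreated libraries 3 and 4 and to 2324 with the batch term. It was 2499 and 2491 without library 3 or 4 alone, against 2895 and 2896 without library 1 or 2, so the number of samples alone does not account for the fall. A fold of at least 2 left 488, 40 and 393 genes in the order above, and an adjusted p under 0.01 left 1545 in PD-L1 high against treated all. Under that threshold the classes of genes changed in both steps held 149 (higher then higher), 493 (higher then lower), 471 (lower then higher) and 76 (lower then lower), and without untreated libraries 3 and 4 they held 176, 552, 545 and 89. Median-ratio scaling gave 124 for the last class. Over the fixed interferon lists the position of PD-L1 high against treated all had the opposite sign, at 0.19. That score used the same genes for every library and the main score did not. The 2 scores also covered different genes, so the signs are not comparable. Risen genes of the interferon lists were more often higher than lower in PD-L1 high, and other risen genes more often lower, as given below. In the other cases the cause was not tested, beyond the stricter thresholds. With an estimated correlation 13 lists held in PD-L1 high against untreated all, against 21. With fry, which tests each list on its own, 28 and 22 lists passed in treated all against untreated all and PD-L1 high against treated all, and in PD-L1 high against untreated all it gave the p53 and CDK inhibitor list (median −0.086) and the stem cell list (median −0.092) the opposite direction to camera, which called neither; the cause was not tested. The replicate numbers did not pair the libraries (correlations of deviations from −0.18 to 0.10). A replicate block gave 6558, 1609 and 5929 genes, where the same 6 libraries without it gave 6483, 2075 and 6240. With the block the IFNγ pathway list passed in PD-L1 high against treated all (camera adjusted p = 0.033) and the RAS-MAPK and YAP list no longer did in PD-L1 high against untreated all (0.055). Count-based tests and a TPM alternative were not run, since no counts were used and the unit is not given. Depth limits could not be assessed.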

Other observations

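The terms of the deposited pathway annotation were tested only after the data were seen, 308 terms with at least 10 tested genes per comparison. In PD-L1 high against treated all, 22 of 108 lysosome genes and 29 of 98 phagosome genes were higher, with 3 and 10 lower (camera adjusted p = 0.0019 for each). On the other side 27 of 70 genes of ribosome biogenesis and 8 of 24 genes of circadian rhythm were lower, with 1 and 0 higher (camera adjusted p = 0.0023 and 0.0019). With an estimated correlation the adjusted p of these 4 terms was 0.73 or more.

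Genes of the fixed interferon lists and the other genes that rose with IFNγ may move apart between treated all and PD-L1 high, a hypothesis formed from the same data. Of 96 interferon-list genes that rose, 47 were higher and 2 lower in PD-L1 high, and of 2552 other genes 222 were higher and 860 lower (Fisher's exact test across genes, two-sided p = 1.3e-28). Genes are not independent replicates, so this p overstates the evidence. The 2 classes also differ in the size of their rise, which was not matched.

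Of 19 symbols held by 2 rows with a value of at least 5, 6 had PD-L1 high values closer to those of treated all when the rows were swapped, against 1 for the untreated values. Rows of 1 symbol were added up for this reason. The strain label was C57BL/6 in 7 libraries and C57BL/7, C57BL/8 and C57BL/9 in the PD-L1 high libraries, a running series like that of a filled spreadsheet column, and it was not used. The 8 libraries whose differences followed 1 factor per gene in 200 of 200 checked rows include the PD-L1 high libraries. In these rows of low signal PD-L1 high thus shared its factor with treated all. If the PD-L1 high values were made apart from the others in some other way, that difference is confounded with the group in both comparisons that use them. It was not tested further.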
